A study of Mus musculus with 5 samples.

How the data were processed

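Total RNA from pooled mouse retinas was measured on 5 Affymetrix whole-genome mouse arrays, 3 of diabetic and 2 of control mice. The groups came from the disease state in the labels, and the replicate numbers from the sample titles. Each array stood for 1 pool of 2 or 3 mice, so a p-value compares pools.

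The deposited values are signal intensities, 1 per probe set, on a linear scale. All 5 columns had the same mean of 2500.0 once the lowest and highest 2% of values were left out, as global scaling gives. The summarization software and its settings are not given in the sources used here, so the background correction behind low values is unknown. Median signals of the arrays ran from 634.6 to 714.7. The table held 45101 probe sets, of which 64 were control probe sets. There were 34945 probe sets with 1 gene symbol, 932 with several and 9160 not listed with a symbol. Symbols were updated by Entrez ID through a gene table of assembly GRCm38.p6, which matched 34741 of them, and 204 kept the symbol of the probe annotation.

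Signals were taken as log2(signal + 120.6), with the pseudocount at the 20th percentile of all values. Fold changes on this scale understate the change of dim genes. The array medians on this scale differed by 0.15, under the limit of 0.2 set for leaving the deposited scaling as it was. Each gene was represented by its probe set of highest mean, giving 18193 genes, and the upper 60% by mean level, 10916 genes, were tested. Diabetic and control arrays were compared with limma (lmFit, and eBayes with a trend), with 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. There were 35 gene lists, and the 29 with 4 or more tested genes were compared by camera with a preset correlation of 0.01, and with fry. These tests, the 35 lists, most alternatives and the rule for named genes were written before the data were examined, and tests and alternatives added later are named as such with their results.

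By that rule, up to 12 genes per direction past the threshold were to be named. With fewer than 20 such genes, the 10 per direction of smallest unadjusted p were taken instead, among genes whose groups did not overlap and whose log2 change was 0.5 or more. Further named genes were the 2 members of smallest p in each list and a fixed set of genes often studied in diabetic retina. Clone names and predicted models were not named.

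The steps were tested on 20 simulated data sets of 10916 genes for diabetic versus control, with gene variances drawn from limma's fitted prior and no correlation between genes. Over the 20 sets, 1000 genes each were changed by 1, 2, 3 and 4 log2 units. Of genes changed by 1 log2 unit 84.9% were recovered, and of genes changed by 2 log2 units 99.4%, with 4.95% false calls. The adjustment is stricter where fewer genes change, and that case was not simulated. These shares therefore do not carry over to the real data, where none of the 15 genes that differed by 1 log2 unit or more passed. A list lowered by 1 log2 unit was called in 20 of 20 sets by camera with the preset correlation. Its simulated members were independent, so this does not carry over to real lists whose members are correlated.

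The alternatives covered quantile normalization, centring on medians, pseudocounts of 1 and 690.0, other filters, the mean over probe sets, other variance models, array weights, a replicate block, each array left out, other thresholds and other list tests. The number of arrays limits the precision. Work was done in R 4.3.3 with limma 3.58.1, and plots were made with matplotlib 3.10.9.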

Results

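Retinal RNA was measured in 3 pools from diabetic mice and 2 pools from untreated control mice of matched age with normal blood glucose. Diabetic replicates 1 and 2 each held 4 retinas of 2 mice, 5 weeks after streptozotocin, a toxin of the insulin-producing beta cells. Diabetic replicate 3 held 6 retinas of 3 mice with induced diabetes of 3 to 4 weeks. Each control pool held 4 retinas of 2 mice. The arrays resembled each other closely, with pairwise correlations across genes from 0.977 to 0.986, although genes are not independent replicates. The highest correlation joined diabetic replicate 3 and control replicate 2.

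The comparison of diabetic with control pools asked which retinal transcripts differ within weeks of diabetes. Among the genes of the largest differences were several of the retinal pigment epithelium, the cell layer behind the photoreceptors that recycles the visual chromophore. Rgr, an opsin of that layer, was at 11.09 ± 0.47 (SD, n = 3) in diabetic and 13.09 ± 0.96 (SD, n = 2) in control pools on the log2 scale, a difference of -1.997 (SE 0.38). Rpe65, the isomerase of the visual cycle, differed by -1.62 (SE 0.33), the retinol dehydrogenase gene Rdh5 by -1.22 (SE 0.27) and Lrat, which esterifies retinol, by -1.49 (SE 0.43). Ttr, which encodes the retinol and thyroid hormone carrier transthyretin, differed by -0.89 (SE 0.20), and all 4 of its probe sets were lower in every diabetic pool than in both controls. Control replicate 2 had the highest values of all 5 genes, and without it the differences were -1.32 for Rgr, -1.06 for Rpe65, -0.68 for Rdh5, -0.72 for Lrat and -0.69 for Ttr. None of these single genes passed the test over all genes (limma, Benjamini-Hochberg adjusted p = 0.999 for each).

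As a group, the fixed list of pigment epithelium and melanocyte genes was lower in diabetic pools, with 8 of 10 tested members lower and a median log2 change of -0.56 (camera adjusted p = 1.70e-07). The call was lost with the estimated correlation of 0.34 between members (adjusted p = 0.891 with an estimated correlation), and fry gave an adjusted p of 0.952. Adjusted over the list alone, 5 members passed, against 0 over all genes tested. These 5 were Rgr, Rpe65, Ttr, Rdh5 and Lrat, while Rrh, an opsin of the same layer, differed by -0.07 (95% interval -0.30 to 0.15). The pigment genes of the same list did not follow the groups. Pmel, a structural protein of melanosomes, was at 12.10, 8.67 and 11.35 in diabetic replicates 1 to 3 and at 9.34 and 12.07 in control replicates 1 and 2. Tyrp1 and Dct, enzymes of melanin synthesis, were also high in diabetic replicates 1 and 3 and in control replicate 2. Lrat, Rrh and the pigment genes were named after their values were seen. The median of the list was -1.35 without control replicate 1, -0.89 without diabetic replicate 1 and -0.38 without control replicate 2. It was -0.31 without the 2 arrays of high skeletal muscle signal, and -0.23 without the filter on dim genes.

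**Figure D1:**
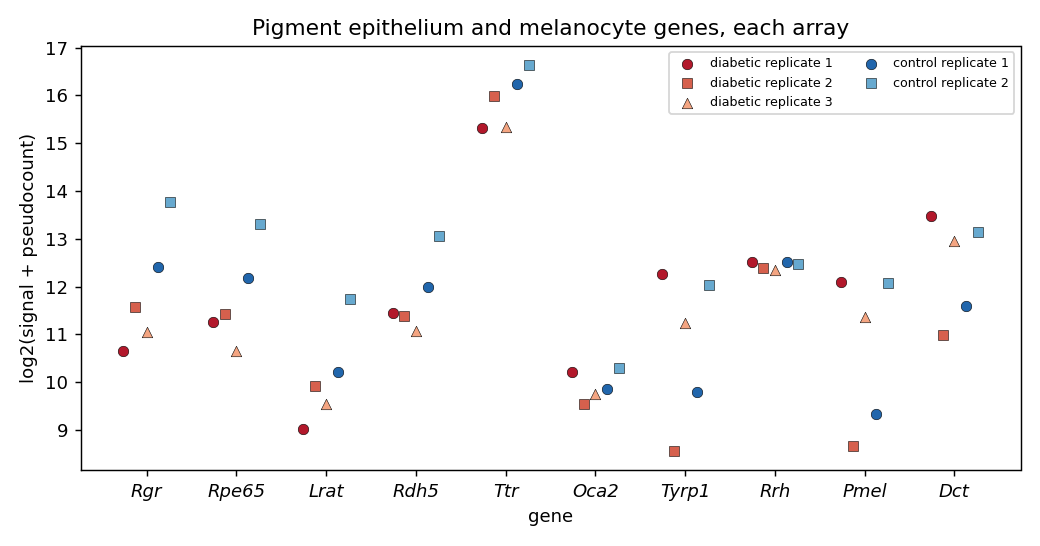
Log2 signal (with pseudocount) of the 10 tested pigment epithelium and melanocyte genes, 1 point per array, red shades for diabetic and blue shades for control pools. Rgr, Rpe65, Lrat, Rdh5 and Ttr lie lower in all 3 diabetic arrays than in both controls, while Tyrp1, Pmel and Dct are high in diabetic replicates 1 and 3 and control replicate 2.

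Across the genome, 0 of 10916 genes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.369. At an unadjusted p under 0.05 there were 370 genes, 196 higher and 174 lower in diabetic pools, where chance alone gives 545.8. The groups did not overlap in 1981 genes, or 18.1%, where chance gives 20%. There were 15 genes that differed by 1 log2 unit or more, 4 higher and 11 lower. The median absolute log2 change was 0.08, below the median standard error of 0.12.

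Among genes with higher values in all 3 diabetic pools, Rbbp9, a serine hydrolase gene, had the smallest p, with a log2 difference of 1.10 (SE 0.14, adjusted p = 0.369). Npl, an enzyme of sialic acid breakdown, differed by 1.32 (SE 0.34) and Prr18 by 1.22 (SE 0.33). Obox6 differed by 0.75, Slc25a40 by 0.64, Mpnd by 0.58, Epdr1 by 0.57, C1ql1 by 0.53, Cox6b2 by 0.53 and Zmat3 by 0.50. Among genes with lower values in all 3 diabetic pools, besides those of the pigment epithelium list, were Slc16a8, Pon1, Col8a1, Crim1, Jun and Itgb8. Slc16a8, a lactate transporter of the pigment epithelium, differed by -1.14 (SE 0.20). Pon1, a paraoxonase, differed by -1.42 (SE 0.32) and Col8a1, a basement membrane collagen, by -0.94 (SE 0.18). Crim1 differed by -0.82, the integrin subunit gene Itgb8 by -0.79 and the transcription factor gene Jun by -0.82, with both Jun probe sets lower. Without control replicate 2, Pon1 differed by -0.80, Itgb8 by -0.51 and Jun by -0.52.

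Genes often followed in diabetic retina had log2 differences between -0.06 and 0.14. Vegfa, the vascular growth factor, differed by 0.01 (95% interval -0.19 to 0.20), Gfap, the intermediate filament of reactive glia, by -0.02 (-0.48 to 0.45), and the glucose-responsive gene Txnip by 0.04 (-0.32 to 0.40). The Muller glia genes Glul, Aqp4 and Kcnj10 differed by -0.06 (95% interval -0.29 to 0.18), 0.14 (-0.08 to 0.36) and 0.07 (-0.25 to 0.38). The cone opsins Opn1sw and Opn1mw differed by 0.07 (-0.13 to 0.27) and 0.09 (-0.15 to 0.33), and Thy1, a ganglion cell marker, by 0.07 (-0.41 to 0.54). With single arrays left out, Glul lay between -0.23 and 0.12, Aqp4 between 0.02 and 0.27, Kcnj10 between -0.06 and 0.15, Opn1sw between -0.01 and 0.15, Opn1mw between 0.02 and 0.16, Thy1 between -0.18 and 0.22, Gfap between -0.12 and 0.09, Txnip between -0.03 and 0.11 and Vegfa between -0.03 and 0.04. Icam1, Aif1, Cryaa and Xist lay below the filter on dim genes and were not tested, and Hbb-b1 is not analysed here. Of 42 named genes with more than 1 probe set above that filter, 13 had probe sets that differed in opposite directions, among them Vegfa, Glul, Opn1sw and Cryab.

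No other list passed (camera adjusted p of 0.162 or more), and in all 28 of them leaving out 1 array moved the median by over 1.5 times or changed its sign. Of the lists for neurons and glia, ganglion cell genes had 12 of 15 members higher (median 0.07, adjusted p = 0.232), with Nefl at 0.15 and Nefh at -0.26 (-0.15 without control replicate 1 and -0.17 without diabetic replicate 2). Reactive gliosis genes had 11 of 16 higher (median 0.07, adjusted p = 0.232), with Edn2 at 0.51 and S1pr3 at 0.26 (0.14 without control replicate 2), and passed without diabetic replicate 2 (median 0.16, adjusted p = 0.0474, and adjusted p = 0.937 with an estimated correlation). Rod phototransduction genes had 13 of 22 lower with a median of -0.00245 (adjusted p = 0.728). The median of this list was -0.07 without control replicate 2 and -0.09 without both arrays of high skeletal muscle signal, fits that leave 1 control array. Its member Rgs9 was at -0.20 (-0.13 without diabetic replicate 3), and Grk1 at -0.27, between -0.48 and -0.16 with single diabetic arrays left out. Cone genes had a median of 0.04 (adjusted p = 0.922), with Pde6h at -0.19 and Slc24a2 at 0.23 (0.09 without diabetic replicate 2 and 0.15 without control replicate 2). The medians were -0.08 for bipolar cell genes (adjusted p = 0.635), 0.07 for amacrine and horizontal cell genes (adjusted p = 0.728), 0.02 for Muller glia identity (adjusted p = 0.868) and 0.03 for synaptic vesicle and ribbon genes (adjusted p = 0.860). Muller glia included Rdh10 at -0.34, and the amacrine and horizontal list Lhx1 at -0.55.

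Of the metabolic and stress lists, hypoxia response genes had 10 of 14 members higher (median 0.08, adjusted p = 0.162), with Pfkfb3 at 0.40 and Bnip3 at 0.13. Polyol, hexosamine and advanced glycation genes had 5 of 7 higher (median 0.04, adjusted p = 0.594). Their member Glo1, the glyoxalase that detoxifies methylglyoxal, differed by 0.77 (SE 0.24), with positive differences in all 4 of its probe sets and groups that did not overlap in 2 of them. Without diabetic replicate 3 the Glo1 difference was 0.48. Circadian clock genes had 12 of 16 higher (median 0.06, adjusted p = 0.312). Unfolded protein response genes had 12 of 15 lower (median -0.04, adjusted p = 0.536), with Asns at 0.25 and Atf3 at -0.22. Apoptosis genes had 5 of 7 lower (median -0.10, adjusted p = 0.316), with Bcl2l11 at -0.30 (-0.07 without control replicate 2 and -0.52 without control replicate 1). The remaining medians were 0.01 for glycolysis (adjusted p = 0.922), 0.02 for oxidative phosphorylation (adjusted p = 0.728), 0.04 for antioxidant response (adjusted p = 0.935), -0.01 for heat shock (adjusted p = 0.922) and -0.01 for ribosomal proteins (adjusted p = 0.853). Glucocorticoid response had a median of 0.02 (adjusted p = 0.999), insulin and IGF signalling -0.00120 (adjusted p = 0.635), and cholesterol and fatty acid synthesis 0.01 (adjusted p = 0.728), with Scd1 at -0.67 (-0.32 without control replicate 2 and -1.02 without control replicate 1). Immediate early genes had a median of 0.00174 and a mean of -0.08 (adjusted p = 0.635), and Jun alone passed when adjusted over the list alone.

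Of the vascular, immune and matrix lists, microglia and macrophage genes had 5 of 6 tested members lower (median -0.25, adjusted p = 0.162), with C1qa at -0.47 (-0.26 without diabetic replicate 3) and Csf1r at -0.36 (-0.18 without control replicate 2 and -0.55 without control replicate 1). The list passed at a median of -0.39 without diabetic replicate 2 (adjusted p = 0.0474), at -0.28 without the filter on dim genes (adjusted p = 0.0214) and at -0.40 with array weights (adjusted p = 0.0430). With an estimated correlation these calls were lost (adjusted p = 0.937, 0.910 and 0.855). Its median was -0.39 without control replicate 1 and -0.10 without control replicate 2, fits that leave 1 control array, and -0.11 without diabetic replicate 3. Interferon response and MHC class I genes had 5 of 7 lower (median -0.08, adjusted p = 0.536), with H2-D1 at -0.28 (-0.12 without control replicate 2 and -0.45 without control replicate 1). All 9 probe sets of H2-D1 were lower, by -0.06 to -2.40. Its probe sets at -2.40, -2.27 and -1.76 were low in diabetic replicates 1 and 2 but not in diabetic replicate 3. The first of these was at 7.38, 7.41 and 11.29 in diabetic replicates 1 to 3 and at 11.14 and 11.05 in the controls. The 4 probe sets of H2-K1 differed by -0.25 to 1.07. Vascular endothelium genes had 7 of 9 higher (median 0.10, adjusted p = 0.728), although Plvap was at -0.29 (-0.13 without diabetic replicate 2). Pericyte and smooth muscle genes had a median of -0.02 (adjusted p = 0.922). Basement membrane and matrix genes had a median of 0.06 and a mean of -0.05 (adjusted p = 0.892), with Col4a1 at 0.24 and Col1a2 at -1.13 (-0.55 without control replicate 2 and -1.71 without control replicate 1). Fewer than 4 members were tested of the crystallin, lens fibre, cornea, erythrocyte, inflammation and sex-linked lists, which therefore had no list test. Their tested members included Cryab at 0.23, Hsf4 at 0.71, Perp at -0.58 (-0.35 without control replicate 2), Vcam1 at 0.05 and Cxcl1 at -0.31. With single arrays left out, Cryab lay between 0.12 and 0.36, Vcam1 between -0.01 and 0.13 and Cxcl1 between -0.92 and 0.31.

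**Figure D2:**
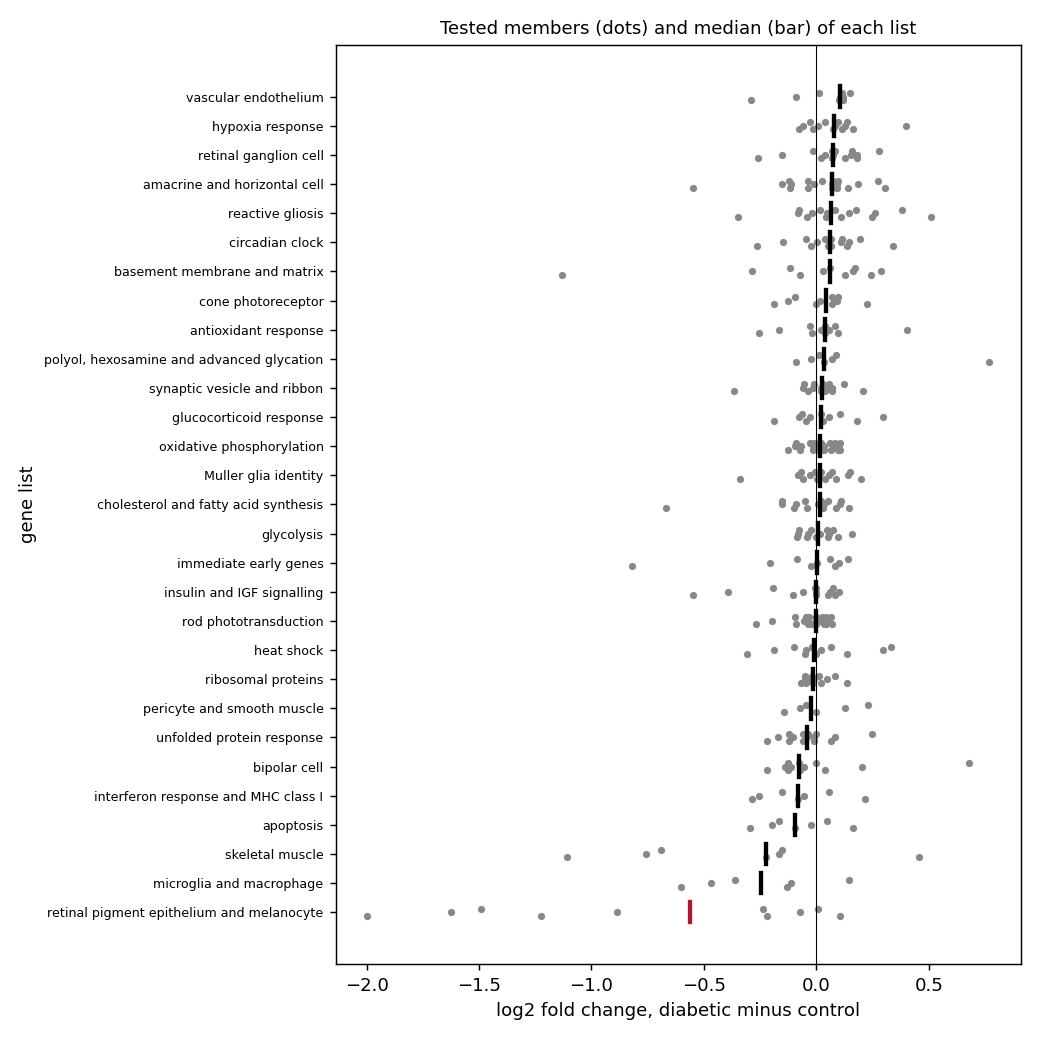
Log2 fold change (diabetic minus control) of each tested member of the 29 lists, as grey dots, with the list median as a bar, red for the list that passed camera with a preset correlation. The pigment epithelium and melanocyte list has its median at -0.56, and the medians of the other lists lie between -0.25 and 0.10.

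Skeletal muscle genes split the arrays across the groups. All 7 tested members of that list were high in diabetic replicate 3 and control replicate 2 and low in the other 3 arrays. Myl1, a fast muscle myosin light chain, was at 14.04 and 13.14 in these 2 arrays and at 7.21, 7.27 and 8.09 in the others. Between diabetic and control pools the list had a median of -0.23 (adjusted p = 0.728), which rested on single arrays, and the correlation estimated between its members was 0.985. The median was -1.63 without diabetic replicate 3 (adjusted p = 5.98e-05) and -1.63 with a replicate block (adjusted p = 1.55e-07), and these calls were lost with an estimated correlation (adjusted p = 0.836 and 0.948). The medians are equal because no control has that replicate number, so the block leaves diabetic replicate 3 out of the comparison. It was -1.85 without control replicate 1 and 1.47 without control replicate 2, fits that leave 1 control array. It was 0.23 without diabetic replicate 1 and 0.41 without diabetic replicate 2. Both arrays with high muscle signal also had high pigment gene signal, which diabetic replicate 1 shared without the muscle genes.

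**Figure D3:**
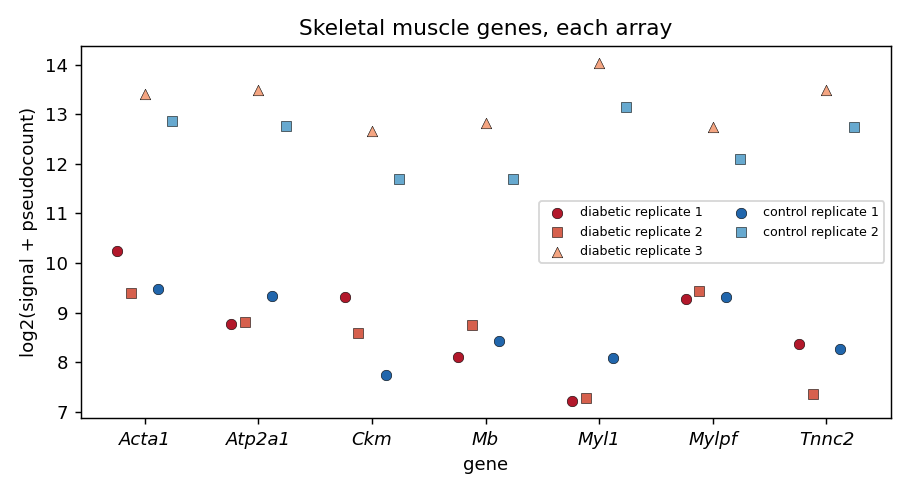
Log2 signal (with pseudocount) of the 7 tested skeletal muscle genes, 1 point per array, red shades for diabetic and blue shades for control pools. In every gene diabetic replicate 3 and control replicate 2 lie above the other 3 arrays, as for Myl1 at 14.04 and 13.14 against 7.21, 7.27 and 8.09.

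RNA quality measures set diabetic replicate 2 apart. Its ratio of 3' to 5' beta-actin control signal was 4.32, against 2.01 to 2.71 in the other arrays, while its Gapdh ratio of 0.901 lay near their 0.784 to 0.838. Y-linked transcripts were measured in every array, with Eif2s3y between 12.58 and 13.30 and Uty between 11.66 and 12.02 on the log2 scale.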

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

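The tests of the muscle split on the pigment epithelium genes, of tissue from behind the retina, and of scaling were chosen only after the results were seen.

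Control probe sets outside the gene comparison gave a signal above both control arrays in diabetic replicate 2. Its 18S ribosomal RNA signals were 11744 at the 3' end, 7087 in the middle and 11259 at the 5' end, or 3.92, 3.64 and 5.83 times the higher control array. Its beta-actin 3' to 5' ratio of 4.32 was 1.60 times the higher control. No biological explanation was tested for these values.

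Pigment epithelium genes were lower in the diabetic pools, by a median of -1.36 over the 6 pigment epithelium members of the list (-0.70 without control replicate 2), against -0.11 over its 4 melanosome members (-1.002 to 0.89 with single arrays left out). Less pigment epithelium was tested on 7 further genes of that layer, whose median of -0.34 (SE 0.19) lay 1.81 standard errors below 0, short of the 2 set beforehand. This SE comes from resampling the 7 genes and does not measure the spread between pools. The distance was 2.08 without diabetic replicate 2, 1.71 without diabetic replicate 1 and 1.00 without diabetic replicate 3. It was 0.85 without control replicate 1 and 0.84 without control replicate 2. The median was -0.16 without control replicate 2 (4 of 7 lower) and -0.20 without diabetic replicate 3. The neural retina also expresses some of these genes, which leaves the test weak and this explanation open. Less tissue from behind the retina as a whole cannot be told apart either, since the 95% interval of only 1 of the 4 melanosome genes excluded a fall as large as -1.36, while without control replicate 2 the intervals of 0 of 4 excluded -0.70, and without diabetic replicate 2 those of 4 of 4 excluded -1.48. With the muscle split as a block in the fit, the median of the fixed list was -0.55 (camera adjusted p = 2.29e-06, and 0.996 with an estimated correlation) against -0.56 without the block. The 95% intervals of 5 of its 10 genes lay below 0 (Rgr, Rpe65, Lrat, Rdh5 and Ttr, but not Rrh at -0.09 or the 4 melanosome genes). The median of the muscle list moved from -0.23 to 0.29. A shift by the split that is the same in both groups therefore did not account for the lower list median. The high side held an array of each group, diabetic replicate 3 and control replicate 2, so only a large shift could move the group difference much. A muscle effect that differs between the groups was not tested and stays open. The block assumes 1 common difference on both sides of the split. The median of the 6 pigment epithelium members was -2.09 in diabetic replicate 3 minus control replicate 2. In the mean of diabetic replicates 1 and 2 minus control replicate 1 it was -0.67. The 10 splits of 5 arrays are too few for a share under 0.05 (only the real groups reached a -log10 p of 8.23, and the highest other was 7.52), and the diabetic state also stays open.

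Skeletal muscle genes were high in diabetic replicate 3 and control replicate 2, by a median of 4.15 over all 13 list members. A candidate explanation is muscle tissue around the eye carried into these 2 pools. It was tested on 17 further muscle genes, whose median was higher by 1.72 (SE 0.53, over genes and not pools), with 16 of 17 higher in the mean of the 2 arrays. Only 2 of the 17, Tnnc1 and Cacna1s, lay above the filter on dim genes. In these, control replicate 2 was at 9.84 and 10.51, below diabetic replicate 2 at 9.95 for Tnnc1 and diabetic replicate 1 at 10.53 for Cacna1s. A scaling difference is argued against, since it would move all genes alike, while the 7 tested list members exceeded the median difference of all tested genes by 3.09 to 6.07, against a 99th percentile of 0.51 over all tested genes. A split of the 5 arrays along this line gave 12 genes at an adjusted p under 0.05, against 0 for the real groups, but the line was drawn from the muscle genes, 7 of the 12 are on the fixed muscle list, and the count restates the pattern.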

How the results depend on the processing

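Leaving out the 2 arrays with high muscle signal, a block for them, the split of the pigment list and estimated correlations with these and other alternatives were chosen after seeing the data. The count of 0 genes past the adjusted threshold was also found with quantile normalization, centring on medians, other pseudocounts, other filters, other variance models, array weights, all probe sets and a threshold of 0.10. It was 2 with the replicate block (Rgr and Spc25), and 0 to 1 when single diabetic arrays were left out (Prss22 without diabetic replicate 2, Spc25 without diabetic replicate 3). Without a control array, or without both high-muscle arrays, 1 control array remains and the diabetic arrays alone set the spread. Adjusted counts from those fits are not given. The replicate numbers were not taken as pairing the pools, since only 2 pairs exist and their deviations correlated at 0.13 and -0.14. At an unadjusted p under 0.05, the 370 genes became 695 without a filter, 214 in the upper 40% of genes and 778 over all probe sets, as the number tested changed. They became 579 with array weights and 208 without both high-muscle arrays, and ranged from 231 to 606 with single arrays left out, the highest without diabetic replicate 2.

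The count of 1 list was 0 with estimated correlations, 2 without a filter, 2 with array weights, 2 with the replicate block, 2 without both high-muscle arrays, and 1 to 3 with single arrays left out. The added lists were microglia, skeletal muscle, rod phototransduction and reactive gliosis, in 10 calls, of which 0 held with an estimated correlation. Every other split of the arrays into groups of the same sizes also gave lists past the threshold, from 1 to 6, against 1 for the real groups. The number of lists called by camera with the preset correlation therefore did not set the real groups apart. The pigment epithelium list stayed lower in all 19 alternatives. It passed in 18, none of which tests the preset correlation they share. With an estimated one it did not (median -0.56, adjusted p = 0.891). Its median ranged from -1.35 (without control replicate 1) to -0.38 (without control replicate 2) with single arrays left out, and was -0.23 without a filter. With both control arrays kept, its camera adjusted p ran from 1.91e-10 (with the replicate block) to 0.891. Its pigment epithelium part alone had an unadjusted p of 0.027 with an estimated correlation, on members chosen after their values were seen.

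Of the 91 named genes, those with an unadjusted p under 0.05 kept their sign in all 560 alternative values, and the others changed sign in 43 of 1047. The genes under 0.05 all had groups that did not overlap, in part by the rule for named genes. Such genes must keep their sign with a single array left out, and under another pseudocount, filter or variance model. For these alternatives the kept signs were fixed beforehand and do not show robustness. Medians of lists changed sign in 66 of 547. The robust variance model and the probe set level gave no list values. The causes were not tested except where fewer genes or arrays entered. Depth has no count here, and dim genes lie near the pseudocount, which shrinks their differences.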

Other observations

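The tests on Glo1 were chosen only after its values were seen, and the genes named here were chosen after their values were seen. Dcn, which encodes the matrix proteoglycan decorin, was at 10.76, 7.49 and 10.22 in diabetic replicates 1 to 3 and at 8.72 and 11.53 in control replicates 1 and 2, high in the same arrays as the pigment genes. The 370 genes at an unadjusted p under 0.05 were matched or exceeded in 8 of the 10 splits of the 5 arrays, the real groups included, with 776 genes in the highest other split, and 10 splits are too few for a share under 0.05. Igfbp5 was at 12.99 in control replicate 2 and between 11.81 and 11.93 in the other 4 arrays.

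Single genes differed in steps between pools, and 46 genes had a gap of 1 log2 unit or more between neighbouring sorted values, among them muscle genes and Rgr, Rpe65, Lrat, Rdh5 and Pon1, whose gap set control replicate 2 apart from the other 4 arrays, control replicate 1 included. Prss22 was at 9.16 and 8.94 in diabetic replicates 1 and 3 and between 12.90 and 13.79 in the other arrays, and Spc25 was at 9.27 and 9.48 in diabetic replicates 1 and 2, the pools of 5 weeks, and between 12.73 and 13.16 elsewhere. Mice of different genetic background could place such genes next to each other on the chromosomes, and 2 neighbouring pairs were found where 0.957 are expected (permutation p = 0.252), but 16 of the 46 genes were tissue markers, and without them there were 0 pairs where 0.398 are expected, too few to decide. This test used 1 probe set per gene. It did not include the H2-D1 probe sets that were low in diabetic replicates 1 and 2 only, as was Spc25. Whether those steps are genetic was not tested. For Glo1, a fault of 1 probe set is argued against by positive differences in all 4 of its probe sets. The smallest, 0.56, rested on diabetic replicate 3, at 12.87. That probe set was at 11.71 and 11.05 in diabetic replicates 1 and 2 and at 11.50 and 11.12 in the controls. A genetic gain of the segment around Glo1 could not be decided. Of its 2 neighbours, 1 reached 50% of the Glo1 change, Dnah8 at 0.93 (95% interval 0.02 to 1.84, in a fit without the filter on dim genes, below which it lay, and with 8.66 in diabetic replicate 2 against 8.63 in control replicate 2), and Btbd9 was at 0.12 (-0.14 to 0.38).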
